A study of Mus musculus with 14 samples.

How the data were processed

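MicroRNA (miRNA) levels were measured on 14 Agilent mouse miRNA arrays, each hybridized with Cy3-labelled RNA. Bone marrow gave 10 arrays and hypothalamus 4, from male C57BL/6 mice 12 h after 0 or 8 Gy of gamma radiation. Every array was a pool of 3 mice, and each combination of tissue, pretreatment, route and dose had 1 array. The labels state pooling of RNA per array, and the series design states it for bone marrow. Pretreatments were phosphate-buffered saline (PBS) given into the abdomen (i.p.) or the stomach (i.g.), amifostine, CBLB502 and nilestriol. Hypothalamus was arrayed for i.p. PBS and amifostine alone.

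The deposited scanner files hold fluorescence intensity per spot, made by the authors with Agilent Feature Extraction 10.7.1.1. Per the file headers the background was subtracted as a fitted surface, and the processed signal intensity equalled the background-subtracted one. The deposited value table is on a log2 scale and gives 1 value per miRNA and array. Its values followed the rank of the summed totals of detected probes (Spearman at least 0.999987 on each array, across miRNAs, which are not independent replicates). Each of its columns had the same upper quartile of 3.43, and miRNAs called not detected shared 1 low value per array. The medians of its columns differed, from -3.32 to -2.77, so how the table was scaled stays unclear here. The total signal per miRNA that the scanner software wrote carried over from the preceding miRNA for 68 to 154 miRNAs per array, so spots were summarised anew.

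For each of the 1247 miRNAs the processed signal of its spots was averaged per probe, leaving out spots marked as outliers (4.42 to 5.27% of the 49880 non-control spots per array), and then over its probes. Signals were divided by the array's 75th percentile over the miRNAs detected on all arrays of the fit, which were 296 for bone marrow, 471 for hypothalamus and 277 for the matched arrays of both tissues. Values below a floor were raised to it before taking log2. The floor was the median over arrays of the 5th percentile of the detected miRNAs' scaled signal, at log2 -5.31 for bone marrow, -5.28 for hypothalamus and -5.61 for the matched arrays. At the floor lay 7.52%, 8.92% and 21.1% of the tested values. A miRNA was detected where the scanner software called it so, with a probe total above 3 times its error, and was tested where detected on at least 1 in 2 arrays of the fit. The floor and the removal of outlier spots were decided after the scanner files had been opened and before any test was run; all other main choices, the comparisons and the lists were fixed before the data were examined.

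Tests were run with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package (version 1.17.8), and p-values were adjusted by Benjamini-Hochberg at 0.05 within each test. All tests were two-sided. Bone marrow irradiation was fitted on 10 arrays with the pretreatment arm (5 levels, both PBS routes apart) as block, and on the 4 PBS arrays alone. Each drug was compared with the 4 PBS arrays over both doses, with dose as covariate. A model of 8 group means gave the drug differences at 8 Gy and the drug by irradiation differences; there a lone drug array was assumed to vary like the PBS pairs. Hypothalamus was fitted for dose and amifostine, the tissue difference on the 8 arrays of the conditions present in both tissues with condition as block, and the tissue by irradiation difference on the same 8 arrays. Each drug array was also set beside the PBS array of its route, dose and tissue, without a test, and miRNAs that differed by 1 or more (log2) in the same direction at both doses were counted.

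The arrays lay on 3 slides. Slide 1 held the bone marrow PBS and CBLB502 arrays and the hypothalamus PBS arrays, slide 2 the bone marrow amifostine and nilestriol arrays, and slide 3 the hypothalamus amifostine arrays, and each slide was a scan batch of its own. Doses were balanced within slides. A slide term could be fitted for the tissue difference; amifostine and nilestriol cannot be told apart from slide.

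The 19 lists of miRNAs were p53 responsive, miR-17-92 and paralogs, miR-15/16 family, let-7 family, erythroid, myeloid, lymphoid, progenitor, inflammation, stromal and endothelial, muscle, liver, neuronal, oligodendrocyte, pituitary and epithelial, choroid plexus and ependyma, the Dlk1-Dio3 cluster, the Sfmbt2 cluster, and GC-rich, late annotated miRNAs. Of 239 list entries, 229 were on the array, 10 of them under another name. Lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01 and adjusted over the lists. The same tests were run with an estimated correlation and with fry. List tests of the vehicle arms, of hypothalamus amifostine and of the tissue difference were not planned.

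For bone marrow irradiation the text names the 12 highest and the 12 lowest log2 differences among miRNAs that passed and had the same sign in all 5 arms. For the other tests it names the 5 highest and 5 lowest that passed or, where fewer than 3 passed in a direction, the 3 with the smallest p in that direction. List members serve as examples, largest differences first, up to 6 per list, and any member of the p53, muscle, liver and neuronal lists. In the comparison without a test, the 3 highest and 3 lowest per drug may be named. Where a miRNA was at the floor or not detected on an array of the lower side of a contrast, its difference is given as a lower bound ("at least"). Where this held on both sides no size is given. List medians count such values.

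Positions are those the scanner files list for a probe. The header names build mm9, but the listed positions mix builds. One is therefore given, the first listed, only where the files list exactly 2 and the second lies in the RefSeq gene (GRCm38) of that miRNA, and the first is then taken as mm9, which held for 145 of 266 names looked at. Sites within a transcript were not annotated here.

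Alternatives covered other scalings (75th percentile over all miRNAs or over the 268 detected on all 14 arrays, quantile normalization, no scaling), normexp background with an offset of 50, an offset in place of the floor, other detection filters, the brightest probe, the software's totals, the authors' value table, a variance trend, other blocks and vehicles, and leaving out each array or arm. After the data were seen, the removal of a straight line on probe GC content, the sum of detected probe totals, fits within a slide and the array's name for miR-486b in the lists were added. The tests were also checked on simulated data with 10 simulations each: a log2 difference of 1 was recovered for 95.4% of changed miRNAs in bone marrow irradiation, 87.1 to 89.0% in the drug comparisons, 59.3 to 59.5% in the drug by irradiation differences and 9.67% in hypothalamus irradiation. False calls made up 2.50 to 5.23%. In the simulated data 123 of 371 miRNAs were changed (181 of 544 in hypothalamus), by 0.5, 1 or 2, with independent normal noise. With so large a share changed the adjustment is milder than where few miRNAs change. Recovery is therefore likely overstated for tests with few calls. The number of arrays limits the precision, replicates are pools of 3 mice, and p-values measure only the spread between these arrays. Where the arrays that give the spread lay at the floor, it was not measured.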

Results

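The data are miRNA profiles of bone marrow and hypothalamus taken 12 h after gamma irradiation of mice that had first received a vehicle or 1 of 3 radioprotective drugs. Bone marrow had 5 pretreatment arms (PBS i.p., PBS i.g., amifostine, CBLB502 and nilestriol), each with 1 array at 0 Gy and 1 at 8 Gy. Hypothalamus had the PBS i.p. and amifostine arms at both doses. Amifostine, a thiol prodrug that scavenges radicals, was given at 10 mg/kg i.p. 0.5 h before irradiation. CBLB502, a flagellin derivative that activates Toll-like receptor 5, was given at 0.2 mg/kg i.p. 0.5 h before, and nilestriol, a long-acting oestrogen, at 150 mg/kg i.g. 48 h before. Of 1247 miRNAs, 332 to 403 were detected on each bone marrow array and 478 to 582 on each hypothalamus array. The median signal of the detected miRNAs lay between 43.6 and 66.4 intensity units in bone marrow and between 64.3 and 83.3 in hypothalamus, and no miRNA was saturated. Changes below are log2 differences ± SE. The prefix mmu- of the miRNA names is left out.

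The first comparison asked what 8 Gy did to bone marrow, across the 5 arms. The largest rise was that of miR-34a-5p, a direct p53 target (chromosome 4, 149442585 to 149442603, in Mir34a), by 2.17 ± 0.13, or 4.49-fold (adjusted p = 0.00108 with limma). Its 8 minus 0 Gy differences were 1.91 with PBS i.p., 1.93 with PBS i.g., 2.28 with amifostine, 2.08 with CBLB502 and 2.63 with nilestriol (SD 0.30, n = 5 arms). All 4 measured members of the erythroid list rose. Among them were miR-144-3p by 1.60 ± 0.34 (3.03-fold) and miR-451a by 1.40 ± 0.17 (2.65-fold), which accumulate as red cell precursors mature. The lymphoid miRNAs miR-181b-5p and miR-181a-5p fell by 1.02 ± 0.13 and 0.67 ± 0.13. miR-363-3p, of the miR-106a-363 cluster on chromosome X (50094922 to 50094940), was detected on 5 of 5 arrays at 0 Gy and on 0 of 5 at 8 Gy, which makes it at least 2.88-fold lower.

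Of 371 miRNAs tested for bone marrow irradiation, 47 passed, 34 higher and 13 lower, each with the same sign in all 5 arms. With 5 differences a miRNA of mixed sign can hardly pass, so the shared sign adds little to the calls. Over 24 alternatives miR-34a-5p lost its call in 2, miR-451a and miR-181b-5p in 5, miR-181a-5p in 8, miR-144-3p in 10 and miR-3069-3p in 18. Besides those above, miR-3107-5p rose by 1.41 ± 0.17, miR-3102-5p by 1.07, miR-30a-5p by 1.02, miR-186-5p by 0.95 (reversed, like miR-486-3p and miR-677-5p, with the scanner software totals), miR-22-3p by 0.90 and miR-877-5p by 0.90. miR-486-3p rose by at least 1.25 (detected on 4 of 5 arrays at 0 Gy) and miR-3107-3p by at least 1.05 (3 of 5). The name miR-3107 is that of miR-486b on this array, and it entered the lists only in an alternative added later. miR-144-5p rose by 0.97. miR-5099 fell by 1.18 ± 0.14, miR-677-5p by 1.05, miR-5117-5p by 0.99, miR-362-3p by 0.69, miR-712-5p by 0.62, miR-1949 by 0.61 and miR-3069-3p by 0.48. miR-3078-5p (detected on 1 of 5 arrays at 8 Gy) and miR-712-3p (4 of 5) fell by at least 1.03 and 0.97. Within slide 1 (3 arms) 10 miRNAs passed, 8 of them among the 47, and miR-34a-5p differed by 1.99. Within slide 2 (2 arms) 0 passed with limma, 102 had an unadjusted p under 0.05, and miR-34a-5p differed by 2.49. The count was 1 without the PBS i.p. arm, 2 without amifostine, 7 without CBLB502, 24 without PBS i.g. and 89 without nilestriol, and quantile normalization turned its balance to 19 higher and 23 lower.

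**Figure D1:**
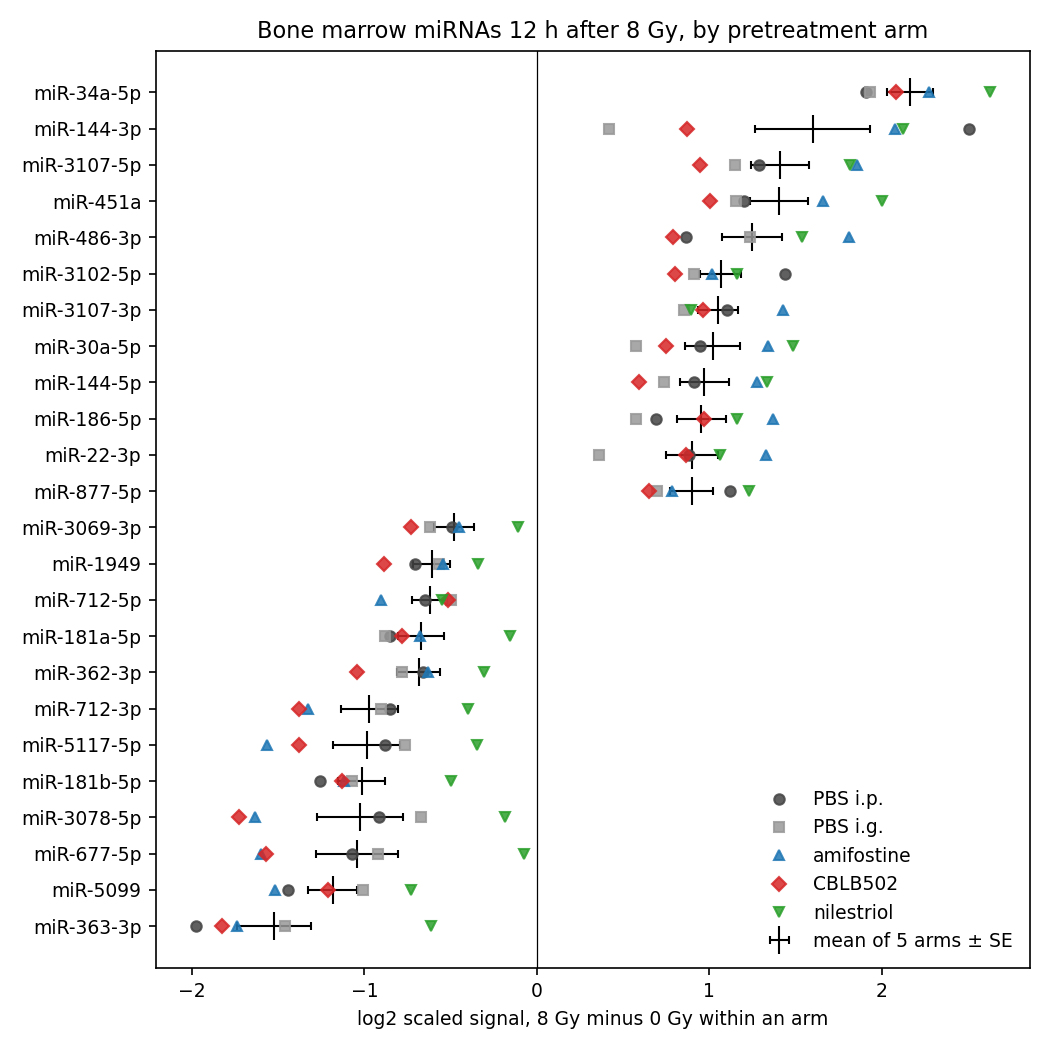
Log2 difference between 8 and 0 Gy of the 24 named miRNAs in bone marrow. Points are the 5 pretreatment arms and bars the mean with its SE; miR-34a-5p lies between 1.91 and 2.63 in every arm.

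By list, camera called 5 of the 15 lists with enough members, relative to all other miRNAs. Erythroid miRNAs were higher (adjusted p = 0.00904), with 4 of 4 risen, 4 also adjusted over the list alone, and a median of 1.33. The p53 responsive list was higher (adjusted p = 0.0112): miR-34a-5p and miR-194-5p (0.64 ± 0.12) rose, and 4 of 4 passed adjusted over the list alone, with miR-192-5p at 0.37 and miR-107-3p at 0.34. In the miR-15/16 family, whose members restrain the cell cycle, miR-16-5p (0.76), miR-15b-5p (0.60) and miR-15a-5p (0.59) rose out of 6, 4 passed adjusted over the list alone, and the list was higher (adjusted p = 0.0241). The let-7 family, regulators of differentiation, was higher in 9 of 9 members with a median of 0.36 (adjusted p = 0.0404). However, 0 passed with limma, over all miRNAs or adjusted over the list alone. let-7e-5p stood at 0.52 ± 0.33 and let-7c-5p at 0.50. The let-7 median was 0.04 with PBS i.p., 0.20 with PBS i.g. and 0.11 with CBLB502, but 0.56 with amifostine and 0.83 with nilestriol. That of miR-15/16 was 0.44, 0.22 and 0.25 against 0.91 and 0.94, in the same order. Both rises were thus larger in the 2 arms of slide 2. In unplanned tests of the vehicle arms alone camera called neither list (adjusted p = 0.318 for let-7 and 0.0967 for miR-15/16). Lymphoid miRNAs were lower (adjusted p = 0.0112): 2 of 8 fell, and 3 passed adjusted over the list alone, miR-150-5p (-0.60) being the third. None of the 5 calls was kept with an estimated correlation (adjusted p = 0.687 with an estimated correlation for each). fry gave adjusted p = 0.0163 for the p53 responsive and erythroid lists and 0.0458 for inflammation.

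The other lists were not called. Among myeloid miRNAs, miR-223-3p (0.54) and miR-21a-5p (0.52) rose out of 7, also adjusted over the list alone (adjusted p = 0.151 for the list). Among progenitor miRNAs, miR-222-3p (0.65) and miR-221-3p (0.48) rose out of 12, 2 also adjusted over the list alone, and 11 were higher (adjusted p = 0.0848). In the inflammation list miR-21a-5p, miR-221-3p and miR-146b-5p (0.44) rose out of 7, and 4 passed adjusted over the list alone (adjusted p = 0.158). In the stromal and endothelial list miR-140-3p (0.71) rose out of 8, 1 also adjusted over the list alone (adjusted p = 0.151). The miR-17-92 and paralogs list, which drives proliferation, moved both ways out of 12: miR-25-3p rose by 0.58 and miR-363-3p fell, with 2 and 2 adjusted over the list alone (adjusted p = 0.378). Muscle miRNAs were at 0.44 (miR-133b-3p), 0.40 (miR-1a-3p) and at least 0.35 (miR-133a-3p), with 0 of 3 passing in limma, over all or adjusted over the list alone (adjusted p = 0.401). In the neuronal list miR-135a-5p rose by at least 0.53 and miR-128-3p was at -0.42, and these 2 and miR-212-3p, at the floor or not detected on arrays of both doses, passed adjusted over the list alone (adjusted p = 0.527). Of 3 oligodendrocyte miRNAs 0 passed and 1 did adjusted over the list alone, miR-338-3p at 0.53 (adjusted p = 0.589). The Sfmbt2 cluster was lower in 6 of 7 members with 0 passing either way (adjusted p = 0.0848). The remaining member, miR-466i-5p (0.32), has its listed position on chromosome 13, while that of miR-467b-5p is on chromosome 2. Of the GC-rich, late annotated miRNAs 2 of 19 rose, miR-3960 by 0.78 and miR-5126 by 0.57, both also adjusted over the list alone (adjusted p = 0.420). Single members were measured for liver (miR-192-5p, 0.37) and the Dlk1-Dio3 cluster (miR-370-3p, -0.40), 2 for the pituitary and epithelial list (miR-7a-5p fell by 0.43 and miR-200c-3p was at 0.47), and none for choroid plexus. These 4 passed adjusted over the list alone, which for a single member is no adjustment. Of them miR-7a-5p alone passed over all miRNAs. Oligodendrocyte and pituitary medians turned sign with the scaling. In the nilestriol arm the muscle and the stromal and endothelial medians were 1.55 and 1.40, the highest of the 5 arms.

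**Figure D2:**
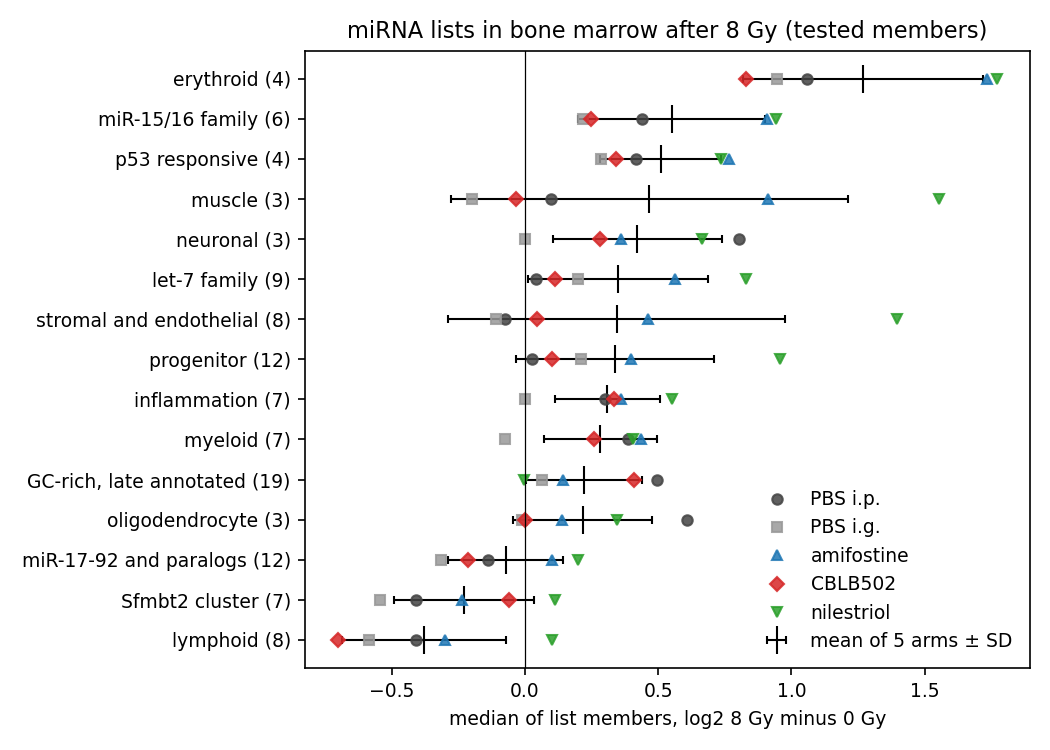
Median log2 difference between 8 and 0 Gy of each list with tested members in bone marrow. Points are the 5 arms and bars their mean with the SD; the erythroid list lies between 0.83 and 1.77, and the lymphoid list below 0 in 4 arms and at 0.10 with nilestriol.

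In the vehicle arms alone, where no drug was involved, miR-34a-5p was 1.94 ± 0.08 higher after 8 Gy (adjusted p = 0.0531) and no miRNA passed. miR-721 was at 1.08, miR-30a-3p, not detected at 0 Gy, at least 1.75-fold higher (though at -0.0074 with normexp background), miR-362-3p at -0.71, miR-5117-5p at -0.81 and miR-3069-3p at -0.54 (adjusted p = 0.0926 for each). With limma 0 of 362 passed and 125 had an unadjusted p under 0.05, where 18.1 would by chance; for bone marrow irradiation, vehicle arms, the count was 17 with the authors' value table, 55 with normexp background and 95 with an offset in place of the floor. In list tests that were not planned, lymphoid miRNAs (8 of 8 lower, median -0.47) and the Sfmbt2 cluster (6 of 7 lower, median -0.46) were lower, with adjusted p = 0.00845 for both. Erythroid (median 1.13) and p53 responsive (0.37) miRNAs were higher, with adjusted p = 0.0319 for both; adjusted over the list alone 5 Sfmbt2 cluster, 3 erythroid and 1 p53 responsive members passed. Each had adjusted p = 0.838 with an estimated correlation.

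CBLB502 was compared with vehicle over both doses, on 2 against 4 arrays of 1 slide for the contrast itself. miR-223-3p, which restrains granulocyte production (chromosome X, 93438225 to 93438244), fell by 0.95 ± 0.13, a 1.93-fold decrease (adjusted p = 0.0277). With it fell miR-27a-3p by 0.75, miR-23a-3p by 0.68 and miR-24-3p by 0.68, the 3 miRNAs of 1 cluster, and miR-10a-5p of the Hox gene clusters by 0.90 ± 0.19. The largest rise was that of miR-494-3p, of the Dlk1-Dio3 region (chromosome 12, 110953585 to 110953598), by 1.28 ± 0.31 or 2.44-fold. miR-466g rose by at least 1.20 (detected on 3 of 4 vehicle arrays), miR-466h-3p by 1.15 ± 0.28, miR-466f-3p by 1.12 ± 0.28 and miR-467f by 1.096 ± 0.28 (adjusted p = 0.0445 for each of these 5). These 5 calls were lost in 13 of 27 alternatives for miR-466g, in 18 of 28 for miR-494-3p and in 21 of 28 for each of the other 3; miR-223-3p lost its call in 9 of 28 and miR-10a-5p in 12.

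In all 45 of 371 miRNAs passed, 20 higher and 25 lower. miR-744-5p fell by 0.91 ± 0.21, miR-340-3p by 0.84 ± 0.13 and miR-467b-5p, detected on 1 of 2 drug arrays, by at least 0.92 ± 0.15; these 3 lost their calls in 16 of 28, 10 of 28 and 10 of 27 alternatives, and the scanner software totals turned miR-467b-5p round. Myeloid miRNAs were lower as a list (adjusted p = 0.00552), with 4 of 7 fallen, 4 adjusted over the list alone and 7 lower; miR-142-3p was at -0.07. Progenitor miRNAs were lower in 12 of 12 members (adjusted p = 0.00895), of which miR-10a-5p fell and 3 passed adjusted over the list alone, with miR-10b-5p at -0.71. The p53 responsive list was lower (adjusted p = 0.0245): miR-194-5p and miR-192-5p fell by 0.78 and 0.62, 3 of 4 passed adjusted over the list alone, and miR-34a-5p was at -0.08. Also lower with adjusted p = 0.0245 were the miR-17-92 and paralogs (11 of 12 lower), miR-15/16 (6 of 6) and let-7 (9 of 9) lists, of which 0 members passed with limma, and 0, 1 and 0 adjusted over the list alone. GC-rich, late annotated miRNAs were higher in 17 of 19 members (adjusted p = 0.0267), with 0 passing either way and miR-5121 at 0.74. With an estimated correlation none of the 7 calls was kept (adjusted p = 0.615 to 0.676 with an estimated correlation), and with fry the myeloid list had adjusted p = 0.0547.

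Lists not called for CBLB502 included lymphoid (0 of 8, adjusted p = 0.0939), erythroid (0 of 4, adjusted p = 0.407), stromal and endothelial (0 of 8, adjusted p = 0.298), and muscle (0 of 3, adjusted p = 0.615), with 0 adjusted over the list alone in each. In lists not called, miR-338-3p of the oligodendrocyte list fell by 0.84 (adjusted p = 0.190 for the list), miR-135a-5p of the neuronal list by at least 0.63 (0.322), miR-192-5p of the liver list as above, and miR-146b-5p of the inflammation list by 0.52 (0.519). The inflammation median was 0.10 while its mean was -0.02 and its test pointed down. This median is the value of miR-21a-3p, at the floor or not detected on arrays of both sides, so it has no firm size. It was negative with scaling over all miRNAs or by quantiles. In the Sfmbt2 cluster 2 of 7 rose and 1 fell, with 2 and 3 adjusted over the list alone, the median was 0.37 and the mean 0.17, and the test pointed down (adjusted p = 0.895). That median is the value of miR-466i-5p, whose listed position is on chromosome 13, while that of miR-467b-5p is on chromosome 2. The differences followed probe GC content (Spearman 0.43 across miRNAs, which are not independent replicates), and with the GC trend removed 2 of the 7 list calls were kept, myeloid and progenitor. Within slide 1 alone 107 passed, 43 of the 45 among them; 0 passed against the i.p. vehicle alone (148 at an unadjusted p under 0.05). The count was 0 without the 0 Gy PBS i.p., 0 Gy PBS i.g., 8 Gy PBS i.p. or 8 Gy CBLB502 array, 21 without the 0 Gy CBLB502 array, and 78 and 88 without the 0 and 8 Gy nilestriol arrays; it was also 0 without scaling, 83 (13 higher and 70 lower) with scaling over all miRNAs, and had 7 higher and 42 lower with quantile normalization.

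**Figure D3:**
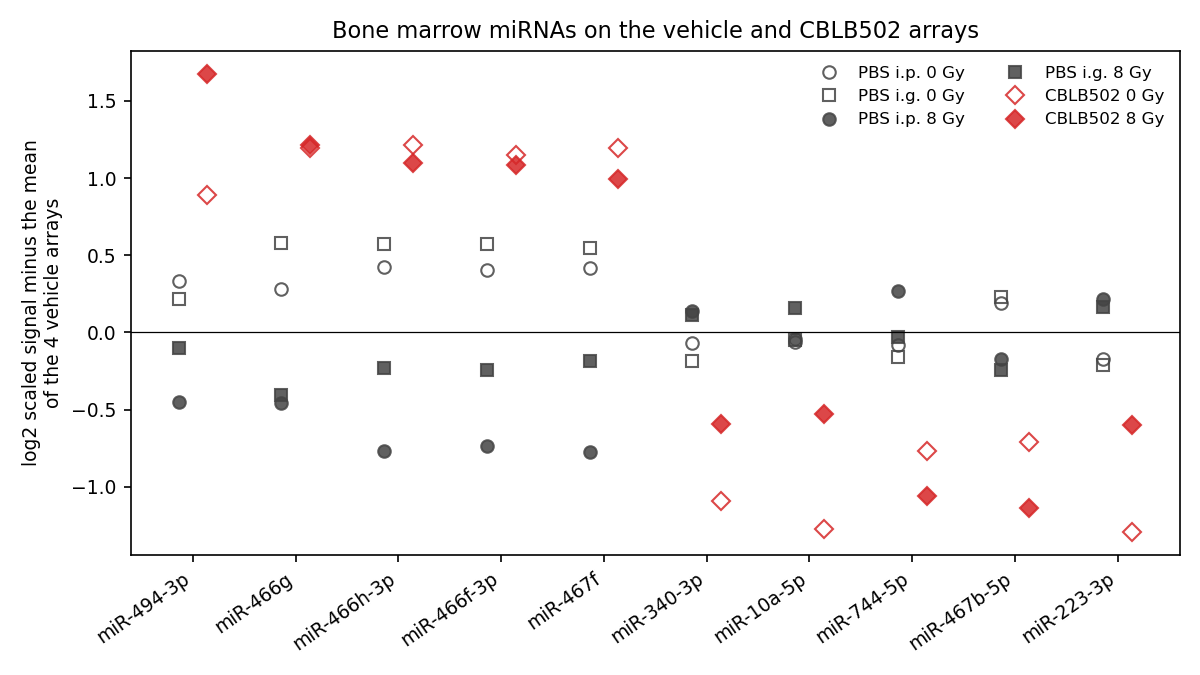
Log2 scaled signal of the 10 named miRNAs on the CBLB502 and vehicle bone marrow arrays, each minus its mean over the 4 vehicle arrays. Points are single arrays at 0 and 8 Gy; miR-223-3p is lower on both CBLB502 arrays.

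Amifostine against vehicle in bone marrow showed lower progenitor miRNAs, 12 of 12 with a median of -0.57 (adjusted p = 6.64e-05), led by miR-126-3p (-0.80), miR-100-5p (-0.80) and miR-10a-5p (-0.67). Myeloid miRNAs were lower in 7 of 7 (median -0.37, adjusted p = 0.00175), with miR-27a-3p and miR-223-3p at -0.51 each, and stromal and endothelial miRNAs in 7 of 8 (median -0.58, adjusted p = 0.0429), led by the miR-126-3p and miR-100-5p that the progenitor list shares. None of 371 miRNAs passed with limma, where 76 had an unadjusted p under 0.05, and up to 13 passed in the alternatives; adjusted over the list alone 0 progenitor, 4 myeloid and 0 stromal members passed. The smallest p were those of miR-3070b-3p (at least 1.94), miR-878-3p (at least 0.98) and miR-6388 (0.69) above vehicle, and of miR-146b-5p (-0.51), miR-223-3p and miR-340-3p (-0.46) below it (adjusted p = 0.133 to 0.142). None of the 3 calls was kept with an estimated correlation (adjusted p = 0.554, 0.554 and 0.746 with an estimated correlation) or with fry (adjusted p = 0.219, 0.219 and 0.511). The erythroid list had a median of 0.08 and a mean of 0.06 against a test pointing down, and the Sfmbt2 cluster a median of -0.15 and a mean of 0.19 against a test pointing down (adjusted p = 0.971 for both); the erythroid and GC-rich medians turned sign with the scaling. Both amifostine arrays lay on another slide than the vehicle arrays, so drug and slide cannot be told apart. The differences followed probe GC content (Spearman 0.39 across miRNAs, which are not independent replicates), and the 3 list calls were kept with the GC trend removed.

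Averaged over both doses, nilestriol arrays showed lower values than vehicle in 6 lists. The miR-17-92 and paralogs list was lower in 12 of 12 members (median -0.42, adjusted p = 0.000576), with miR-25-3p at -0.64. let-7 (9 of 9, median -0.48) and lymphoid miRNAs (8 of 8, median -0.48, miR-181b-5p at -0.70) followed with adjusted p = 0.00316 for both. The miR-15/16 family (median -0.43) and inflammation list (median -0.47, miR-221-3p at -0.74) had adjusted p = 0.0324 each, and erythroid miRNAs (4 of 4 lower, median -0.58, miR-451a at -0.84) adjusted p = 0.0431. With limma 0 of 371 miRNAs passed and 95 had an unadjusted p under 0.05; adjusted over the list alone 2 inflammation and 2 erythroid members passed and 0 in the other called lists. Named by p were miR-1935 (at least 0.96, though reversed with normexp background), miR-1931 (0.84) and miR-6392-3p (0.68) above vehicle, and miR-15b-3p (-0.82), miR-221-3p and miR-146b-5p (-0.61) below it (adjusted p = 0.116 to 0.179). Each list call ended with an estimated correlation (adjusted p = 0.546 with an estimated correlation) and with fry (adjusted p = 0.137). The Sfmbt2 cluster had a median of 0.12 and a mean of 0.03 against a test pointing down (adjusted p = 0.889); its median and those of the oligodendrocyte and GC-rich lists turned sign with the scaling. Without the 8 Gy nilestriol array 95 miRNAs passed, and these arrays, too, shared no slide with vehicle. The 0 Gy array stood apart from its vehicle array: 54 miRNAs differed by 1 or more from PBS i.g. at 0 Gy (SD 0.74 over miRNAs) and 0 at 8 Gy (SD 0.26). Each of the 6 called lists had a higher 8 minus 0 Gy median in this arm than with PBS i.p. and PBS i.g. Examples are erythroid (1.77 against 1.06 and 0.94), let-7 (0.83 against 0.04 and 0.20) and lymphoid (0.10 against -0.41 and -0.58). The averaged differences and the list calls thus lean on the 0 Gy array, and the lists were not tested by dose. The differences over both doses followed probe GC content (Spearman 0.47 across miRNAs, which are not independent replicates), and with the GC trend removed 2 of the 6 list calls were kept, miR-17-92 and lymphoid.

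At 8 Gy alone, the question was how pretreated irradiated mice differed from irradiated vehicle mice, with 1 drug array against 2. The spread came from the PBS pairs alone, and where these lay at the floor none was measured. The SE was then the same 0.0672: for miR-150-3p with amifostine and CBLB502, miR-682 with CBLB502, and miR-125b-1-3p and miR-193b-5p with nilestriol. The p-values of such miRNAs borrow the spread of other miRNAs and measure none of their own. With amifostine miR-504-3p was at least 10.1-fold higher, miR-30c-1-3p higher by at least 1.52 and miR-150-3p by at least 1.03 (adjusted p = 0.0700 to 0.0736), while miR-125a-5p was at least 1.61-fold lower and miR-223-3p and miR-362-3p were at -0.32. The direction of miR-125a-5p and miR-362-3p was reversed with normexp background, and that of miR-30c-1-3p, as that of miR-150-3p with CBLB502, with the scanner software totals. With CBLB502 miR-3061-5p was at least 3.49-fold and miR-682 at least 2.15-fold higher, miR-150-3p higher by at least 1.19, miR-223-3p at -0.79, and miR-467b-5p and miR-467a-3p at least 1.90-fold and 1.81-fold lower (adjusted p = 0.0539 for each). With nilestriol miR-432 was higher by at least 0.86 and miR-125b-1-3p by at least 0.58, miR-193b-5p at least 1.37-fold higher, miR-15b-3p at -0.62, miR-221-3p at -0.60 and miR-146b-5p at -0.54 (adjusted p = 0.474). With limma 0 of 371 passed for each drug, with 40, 123 and 36 at an unadjusted p under 0.05 for amifostine, CBLB502 and nilestriol. These counts depended on the processing, with up to 24, 61 and 11 passing in the alternatives.

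Whether a drug altered the response to 8 Gy was tested as the drug by irradiation difference. The spread came again from the PBS pairs, with the same limit for miRNAs at the floor. With amifostine it was 1.11 for miR-500-3p and -1.104 for miR-690 (adjusted p = 0.242). miR-504-3p, miR-30c-1-3p, miR-193b-5p and miR-682, also named by p, were at the floor or not detected on both sides of the contrast, so no size is given. For CBLB502 it was -0.81 for miR-690 and -0.76 for miR-3096a-5p (adjusted p = 0.348 to 0.421 for the 6 named), and no size is given for miR-664-5p, miR-3061-5p, miR-150-3p and miR-696, for the same reason. With nilestriol it was 1.64 for miR-130a-3p, at least 1.58 for miR-152-3p and 1.25 for miR-151-5p, and -2.74 for miR-714, -1.55 for miR-1224-5p and at least 1.28 downward for miR-711, reversed with normexp background (adjusted p = 0.133). For each drug 0 of 371 passed with limma, with 61, 38 and 85 at an unadjusted p under 0.05, and up to 39, 41 and 52 passed in the alternatives.

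Set beside the single PBS array of the same route and dose, without a test, miR-466g was 1.01 and at least 1.504 higher with amifostine at 0 and 8 Gy, and in the main setting no other bone marrow miRNA differed by 1 or more at both doses; the count was 1 for amifostine, 0 for CBLB502 and 0 for nilestriol. It ranged from 0 to 30, 0 to 35 and 0 to 13 in the alternatives. At 0 Gy 19, 13 and 54 miRNAs differed by 1 or more, and at 8 Gy 17, 40 and 0. The 2 PBS routes differed by 1 or more in 4 miRNAs at 0 Gy and 2 at 8 Gy. In hypothalamus 3 did so at both doses with amifostine (0 to 16 in the alternatives), miR-200a-3p (3.34 and 1.28), miR-200b-3p (3.37 and 1.18) and miR-3113-5p (at least 1.28 and 1.07). Amifostine and CBLB502 differences from the shared PBS i.p. array correlated across the 371 miRNAs, which are not independent replicates. Here r was 0.904 at 0 Gy (covariance 0.294) and 0.687 at 8 Gy (0.237). A simulated shared vehicle alone gave 0.504 (0.0457) and 0.505 (0.0478). The simulated arrays all had equal, independent noise, which by itself fixes r near that value. It is therefore no measure of what the shared array gave here. The Spearman correlation of the amifostine and CBLB502 differences with probe GC content was 0.41 and 0.43 at 0 Gy, and 0.11 and 0.35 at 8 Gy. Such a trend was not simulated. Against different vehicles r was 0.766 and 0.716 at 0 Gy and 0.565 and 0.431 at 8 Gy.

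In hypothalamus no single miRNA passed after 8 Gy, and the widest differences lay in 1 group, high on 1 array. The pituitary and epithelial list, which holds the miR-200 family of epithelial cells, was lower in 10 of 10 members with a median of -1.36 (adjusted p = 5.34e-08), led by miR-200a-3p (-1.96; chromosome 4, 155429062 to 155429079), miR-200b-3p (-1.88) and miR-429-3p (-1.82), while miR-375-3p was at -0.52 and the endocrine and neuronal miR-7a-5p at -0.32. This median counts 3 members at the floor or not detected on arrays of both doses (miR-200c-3p, miR-183-5p and miR-96-5p). It is the midpoint of miR-200c-3p and miR-183-5p, which with PBS lay at the floor at both doses, so it has no firm size. The list call was not kept with an estimated correlation (adjusted p = 0.897 with an estimated correlation) or with fry (adjusted p = 0.980). The 0 Gy amifostine array held miR-200a-3p 11.6-fold above the mean of the other 3 arrays; with PBS its log2 level was -3.78 at 0 Gy and -4.71 at 8 Gy. miR-34a-5p was at 0.25 ± 0.22, with differences of 0.45 with PBS and 0.05 with amifostine. Choroid plexus and ependyma miRNAs were lower in 7 of 7 members (median -0.33, adjusted p = 0.000601), led by miR-34c-5p (-0.47) and miR-34b-3p (-0.44), and this call, too, had adjusted p = 0.897 with an estimated correlation.

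With limma 0 of 544 miRNAs passed and 0 had an unadjusted p under 0.05 (smallest adjusted p = 1), in a test that recovered 9.67% of simulated log2 differences of 1, and no list member passed adjusted over the list alone. Named by p were miR-712-3p (0.48), miR-139-3p (0.30) and miR-34a-5p above 0 Gy, and miR-142-3p (-0.63), miR-375-3p (reversed with the scanner software totals) and miR-34c-5p below it. Lower with adjusted p = 0.0218 were the p53 responsive (9 of 10, median -0.17, sharing the miR-34b and miR-34c members with choroid plexus), miR-17-92 (9 of 9, -0.25), stromal and endothelial (10 of 10, -0.15) and Dlk1-Dio3 (30 of 30, -0.14) lists. These 4 calls were not kept either with an estimated correlation (adjusted p = 0.897 with an estimated correlation) or with fry (adjusted p = 0.980, and 0.263 for stromal). The differences followed probe GC content (Spearman 0.41 across miRNAs, which are not independent replicates), and with the GC trend removed 3 of the 6 list calls were kept, pituitary, choroid plexus and miR-17-92. Not called were miR-15/16 (adjusted p = 0.265), Sfmbt2 cluster (0.273), progenitor (0.404), inflammation (0.740), and muscle, myeloid, neuronal, oligodendrocyte and GC-rich (0.219 each), with muscle at a median of -0.53. let-7 and lymphoid miRNAs (0.533 each) and the GC-rich list had negative medians and means against tests pointing up, and the oligodendrocyte list a negative median against a mean of 0.01 and a test pointing up. Erythroid had 1 tested member (miR-451a, -0.21) and liver 2 (miR-192-5p at -0.14, and miR-122-5p at the floor or not detected on arrays of both doses).

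**Figure D4:**
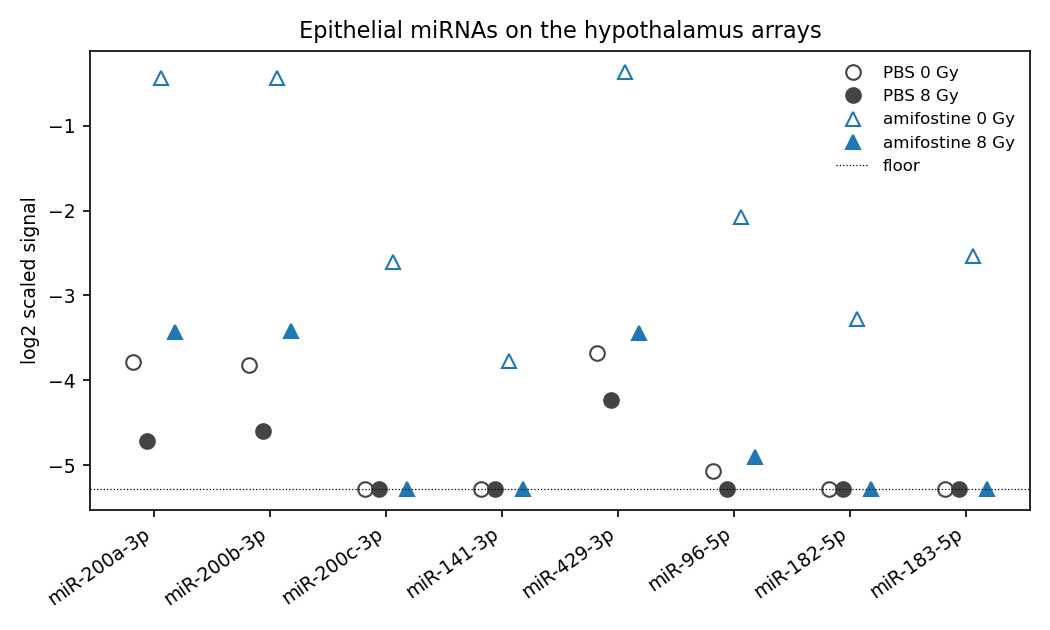
Log2 scaled signal of the 8 miR-200 family, miR-96, miR-182 and miR-183 members on the 4 hypothalamus arrays. Points are single arrays, the dotted line is the floor, and all 8 members are highest on the 0 Gy amifostine array.

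With amifostine against vehicle in hypothalamus no miRNA passed. miR-200a-3p was at 2.31 ± 0.74, miR-3113-5p at least 2.26-fold higher, miR-6236 at 0.89, miR-3092-3p at least 1.61-fold lower, miR-877-3p lower by at least 0.52 and let-7f-1-3p by at least 0.40 (adjusted p = 1). Here 0 of 544 passed with limma (9 with the authors' value table, for hypothalamus amifostine against vehicle) and 1 had an unadjusted p under 0.05. In unplanned list tests the pituitary and epithelial (7 of 10 higher, median 1.36, adjusted p = 0.00544) and muscle lists (4 of 4, median 0.71, miR-1a-3p at 0.75, adjusted p = 0.0328) were higher. Both rest largely on the 0 Gy amifostine array, where 7 of 10 and 4 of 4 members were highest. miR-200a-3p exceeded vehicle by 3.34 at 0 Gy and 1.28 at 8 Gy. miR-200c-3p and miR-183-5p lay at the floor or were not detected on arrays of both sides. The pituitary and epithelial median is their midpoint, as after 8 Gy with the sign turned, so these 2 medians are not separate results. The Dlk1-Dio3 (26 of 30, adjusted p = 0.0117) and Sfmbt2 clusters (10 of 10, adjusted p = 0.0469) were lower, and each had adjusted p = 0.989 with an estimated correlation. Drug and slide cannot be told apart here either.

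Between tissues, bone marrow held far more of the erythroid and of several myeloid miRNAs, and hypothalamus of the neuronal ones. miR-223-3p was 734-fold (9.52 ± 0.29, adjusted p = 1.82e-05), miR-142-3p 175.1-fold and miR-451a 74.7-fold higher in bone marrow, and miR-142-5p and miR-144-3p at least 54.3-fold and 51.4-fold. In hypothalamus miR-124-3p was at least 992-fold higher (adjusted p = 8.71e-06), miR-9-3p 582-fold, miR-9-5p 492-fold, miR-127-3p 438-fold and miR-129-2-3p 426-fold, each at least, since none was detected on the 4 matched bone marrow arrays. The proliferative miR-17-92 list was higher in bone marrow in 11 of 11 members, all passing, with a median of 4.13 (adjusted p = 4.43e-09 in an unplanned list test, and adjusted p = 0.722 with an estimated correlation).

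Of 530 miRNAs tested for the tissue difference 297 passed, 84 higher in bone marrow and 213 in hypothalamus; 232 passed with slide as a block and 238 within slide 1. The balance depended on the scaling, with 242 and 134 when scaled over all miRNAs and 211 and 148 with quantile normalization. In list tests that were not planned, erythroid (4 of 4 passing, adjusted p = 0.00484) and myeloid (4 of 8, adjusted p = 0.00369) miRNAs were higher in bone marrow. Neuronal (17 of 18, median -5.49, adjusted p = 3.41e-06), Dlk1-Dio3 (29 of 30, median -5.10, adjusted p = 5.24e-10) and choroid plexus (6 of 6, adjusted p = 0.0175) miRNAs were higher in hypothalamus. The GC-rich list was higher in bone marrow (8 of 20, median 0.61, adjusted p = 0.00585), and its median was -0.03 without scaling. Not called were the lymphoid (7 of 9 members lower in bone marrow, with 2 higher and 5 lower passing, median -0.98, adjusted p = 0.742) and progenitor lists (10 of 13 lower, with 3 higher and 9 lower passing, median -2.31, adjusted p = 0.196). Adjusted over the list alone 11 miR-17-92, 4 erythroid, 6 myeloid (5 higher and 1 lower), 17 neuronal, 30 Dlk1-Dio3, 6 choroid plexus and 5 GC-rich members passed. The calls had adjusted p = 0.722 to 0.729 with an estimated correlation. For the difference between tissues in the response to 8 Gy, miR-451a (1.66) and miR-139-3p (-0.96) were named by p, with miR-712-3p and miR-3102-3p, lower by at least 1.67 and 0.99 (adjusted p = 1 for each). miR-144-3p and miR-3107-3p were also named, but lay at the floor or were not detected in hypothalamus, so no size is given. For this difference 0 of 530 passed with limma and 21 had an unadjusted p under 0.05, and up to 58 passed in the alternatives.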

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

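The tests of scaling, of the share of lymphoid cells, of slides and of neighbouring tissue, muscle miRNAs included, below were chosen only after the results were seen, as were the members tested for slide, the tests of single arrays of the 10 named tissue miRNAs, and the comparison with nearest arrays. Of 55 groups of 4 or 5 values tested for 1 value far from the rest, 3 held such a value, where chance gives 2.75.

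miR-181a-5p differed by -0.157 between 8 and 0 Gy in the nilestriol arm, against -0.88 to -0.68 in the other 4 arms. miR-181b-5p differed by -0.50 in the nilestriol arm, against -1.26 to -1.07 in the other 4. The bone marrow array of PBS i.p. at 8 Gy had 332 detected miRNAs, against 367 to 380 on the other 4 arrays at 8 Gy.

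Erythroid miRNAs were higher and lymphoid miRNAs lower in bone marrow after 8 Gy as lists in camera, though neither call was kept with an estimated correlation (adjusted p = 0.687 with an estimated correlation for both). Of 8 lymphoid members 2 fell, the lymphoid list had adjusted p = 0.0999 with fry, and its median was 0.10 in the nilestriol arm. Against probe GC content as the whole cause, the erythroid list median stayed at 1.29 (SD 0.33 over 5 arms) with the GC trend removed. Against scaling as the whole cause, with no scaling at all the erythroid list median was 1.21 (SD 0.33, 0.74 to 1.64 in the 5 arms) and the lymphoid one -0.46 (SD 0.29, below 0 in all 5). A lower share of lymphoid cells would raise all other types alike, but erythroid exceeded myeloid medians by 0.98 (SD 0.36). Myeloid members ran from -0.12 (miR-142-5p) to 0.54 (miR-223-3p). Whether all of them are confined to myeloid cells was not tested, so this comparison holds for the lists and does not settle the cell shares. A larger share of late red cell precursors, or altered miRNA levels within cells, may underlie the rise and was not tested; the erythroid median was 0.83 to 1.77 in the 5 arms.

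The miR-200 family, miR-96, miR-182 and miR-183 were higher on the hypothalamus 0 Gy amifostine array, with miR-200a-3p, miR-200b-3p and miR-429-3p 11.6-fold, 11.3-fold and 10.72-fold above the mean of the other 3 arrays. Against a shift of all dim miRNAs, 161 miRNAs of like level outside the list had a median deviation of 0 (SD 0.35), and the 91 of them detected on all 4 arrays one of 0.07 (SD 0.36). Against a difference between slides, the excess over vehicle was 2.29 larger (SD 0.43 over the 8 members, 5 of them not detected on the vehicle arrays) on the 0 Gy than on the 8 Gy amifostine array, which share a slide. Tissue from beside the hypothalamus in that pool may be a source: 7 of 10 tested members of the pituitary and epithelial list were highest there, which leaves this open, since miR-375-3p deviated by 0.75 but miR-7a-5p, which hypothalamus itself holds at a high level, by 0.10. All 4 tested muscle miRNAs were highest there too, with a median deviation of 1.45 (miR-1a-3p 2.74-fold, miR-206-3p at or near the floor on the other 3), so material of more than 1 other tissue is possible. An effect of amifostine on the unirradiated hypothalamus stays untested, with 1 array per condition.

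The bone marrow 0 Gy nilestriol array stood apart by its distance from vehicle and from its nearest array. From the 0 Gy PBS i.g. array 54 miRNAs differed by 1 or more. Its highest correlation with another bone marrow array was 0.972 across miRNAs (not independent replicates), against at least 0.982 for each of the other 9. By its lowest correlation it did not stand apart: 0.950, against 0.947 among the other 9. The 8 Gy CBLB502 array, too, differed by 1 or more from its vehicle array in 40 miRNAs (SD 0.69 over miRNAs). Against probe GC content as the whole cause, 49 still differed with the GC trend removed, although the differences of all 371 tested miRNAs on that array followed GC (Spearman 0.52). Against a difference between slides, 0 differed by 1 or more on the 8 Gy nilestriol array of the same slide. An effect of nilestriol on unirradiated marrow, or something particular to that pool, may account for the 54 and was not tested.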

How the results depend on the processing

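Removing the GC trend, summing the totals of detected probes and fitting within a slide were tests chosen only after the results were seen; the other alternatives, leave-one-out included, were planned. Where a count or a direction changed, the cause was not tested unless stated.

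For bone marrow irradiation 1 of 100 splits drawn of the 10 arrays, the real one, gave as many as 47 miRNAs, and the highest other gave 5. Most of these part fewer arms than the real one. The 16 that part every arm are too few for a share under 0.05, and there the highest other gave 0. For the tissue difference 1 of the 32 splits that could be fitted, the real one, gave 297, and the highest other gave 0. Only 8 of the 32 part all 4 pairs, as the real one does, and the rest part 2. These 8 are too few for a share under 0.05, and there, too, the highest other gave 0. In every other split a real difference adds to the spread and lowers the count. The splits therefore cannot exclude chance for either count. Without the PBS i.p. arm bone marrow irradiation gave 1, without amifostine 2, without CBLB502 7, without PBS i.g. 24 and without nilestriol 89, so leave-one-out counts ran from 1 to 89, with 44 of the 47 kept in the last. miR-34a-5p kept its direction in all 24 alternatives (1.36 to 2.49) and lost its call with no filter and within slide 2 (adjusted p up to 0.176); miR-451a lost it in 5 of 24, miR-181b-5p in 5, miR-363-3p in 7 and miR-144-3p in 10, and for CBLB502 miR-223-3p in 9 of 28 and miR-494-3p in 18.

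Bone marrow irradiation gave 27 with scaling over miRNAs detected on all 14 arrays, 0 with no filter (more miRNAs tested), 30 with the brightest probe, 18 with the scanner software totals, 7 with the authors' value table, 26 with no arm block, 10 within slide 1 and 0 within slide 2 (fewer arrays). The vehicle arms, 0 of 362 in the main test, gave 1 with scaling over miRNAs detected on all 14 arrays, 55 with normexp background, 1 with detection on every array, 5 with software totals, 17 with the value table, 95 with an offset in place of the floor and 1 with GC removed. CBLB502, 45 in the main test, gave 83 with the 75th percentile over all miRNAs, 0 with no scaling, 2 with scaling over miRNAs detected on all 14 arrays, 16 with detection on at least 2 arrays, 0 with no filter, 12 with software totals, 4 with the value table, 68 with an offset, 17 with a variance trend, 21 with the sum of probe totals, 0 with vehicle of the same route, 78 with cell means and 107 within slide 1 (43 of 45 kept). Its leave-one-out counts ran from 0 to 88: 0 without 0 Gy PBS i.p., 0 Gy PBS i.g., 8 Gy PBS i.p. or 8 Gy CBLB502, 21 without 0 Gy CBLB502, 78 and 88 without 0 and 8 Gy nilestriol.

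Amifostine in bone marrow (0) gave 4 with normexp, 13 with an offset and 7 with GC removed. Nilestriol (0) gave 72 with scaling over all miRNAs, 8 with normexp, 1 with the sum of probe totals, and 0 to 95 in leave-one-out fits (95 without the 8 Gy nilestriol array). Hypothalamus amifostine (0) gave 9 with the value table. The tissue difference (297) gave 160 with detection on every array (fewer miRNAs tested). Tissue by irradiation (0) gave 1 with normexp, 4 with the brightest probe, 8 with an offset, and 0 to 58 in leave-one-out fits (58 without 8 Gy PBS, 19 without 0 Gy PBS, 3 and 2 without 0 and 8 Gy amifostine of hypothalamus).

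The tests with 1 drug array, at 0 in the main setting, moved as follows. Amifostine at 8 Gy gave 1 with no scaling, 4 with scaling over miRNAs detected on all 14 arrays, 11 with normexp, 12 with detection on at least 2 arrays, 24 with no filter, 1 with the brightest probe, 7 with software totals, 6 with the value table, 24 with an offset, 4 with a variance trend, 1 with the sum of probe totals and 3 with GC removed. CBLB502 at 8 Gy gave 46 with scaling over all miRNAs, 31 with normexp, 36 with detection on at least 2 arrays, 22 on every array, 30 with no filter, 15 with the brightest probe, 40 with software totals, 18 with the value table, 61 with an offset, 20 with a variance trend, 8 with the sum of probe totals and 34 with GC removed. Nilestriol at 8 Gy gave 11 with no filter, 3 with software totals, 7 with the value table, 6 with an offset and 1 with a variance trend. By irradiation, normexp gave 3, 4 and 14 for amifostine, CBLB502 and nilestriol, detection on at least 2 arrays 17, 12 and 10, no filter 39, 41 and 27, software totals 8, 9 and 17, the value table gave 9, 8 and 12, an offset 3, 8 and 52, and a variance trend 10, 5 and 6; the brightest probe gave 1 for amifostine.

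The 5 lists called for bone marrow irradiation became 3 with quantile normalization, 3 with the value table, 0 with an estimated correlation and 3 with fry (2 of the 5, p53 responsive and erythroid, and inflammation, not called in the main setting). The 3 of amifostine became 1 with quantile normalization, 0 with an estimated correlation and 0 with fry. The 7 of CBLB502 became 3, 0 and 0 in the same alternatives and 2 with GC removed, and the 6 of nilestriol became 3 (2 of the 6, and progenitor), 0, 0 and 2. The 6 of hypothalamus irradiation became 2 with scaling over all miRNAs, 3 with no scaling, 2 with normexp (1 of the 6, and muscle), 2 with the value table, 0 with an estimated correlation and 0 with fry. Route-matched counts became, for bone marrow amifostine (1), 12 with no scaling, 0 with normexp and 30 with the value table; for CBLB502 (0), 16 with no scaling, 3 with quantile normalization and 35 with the value table; for nilestriol (0), 13 with the value table; and for hypothalamus amifostine (3), 0 with quantile normalization, 0 with normexp and 16 with the value table.

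Named miRNAs reversed 22 times. The software totals, which carry over between miRNAs, reversed mmu-miR-486-3p (-0.079), mmu-miR-186-5p (-0.11) and mmu-miR-677-5p (0.69) for bone marrow irradiation, mmu-miR-467b-5p (1.12) for CBLB502, mmu-miR-30c-1-3p for amifostine at 8 Gy (-4.41) and by irradiation (-4.02), mmu-miR-150-3p for CBLB502 at 8 Gy (-0.28), mmu-miR-682 for amifostine by irradiation (3.45), mmu-miR-664-5p (-1.36) and mmu-miR-696 (2.32) for CBLB502 by irradiation, and mmu-miR-375-3p for hypothalamus irradiation (0.71). With normexp mmu-miR-30a-3p (-0.0074, vehicle arms), mmu-miR-1935 (-0.0071, nilestriol), mmu-miR-362-3p (0.029) and mmu-miR-125a-5p (0.043, both amifostine at 8 Gy), mmu-miR-682 (0.39) and mmu-miR-193b-5p (0.30, both amifostine by irradiation), mmu-miR-696 (0.11, CBLB502 by irradiation) and mmu-miR-711 (0.0058, nilestriol by irradiation) reversed. With the value table mmu-miR-682 (2.39) and mmu-miR-696 (1.15) reversed, and with an offset mmu-miR-682 (0.20). For mmu-miR-30c-1-3p, mmu-miR-193b-5p, mmu-miR-682, mmu-miR-664-5p and mmu-miR-696 the main differences by irradiation rested on values at the floor or not detected, so their direction was not firm.

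Scaling moved the median difference of all miRNAs by over 0.1 as follows. The 75th percentile over all miRNAs moved amifostine from 0.05 to -0.18, CBLB502 from 0.15 to -0.02, nilestriol from 0.02 to -0.16, the 8 Gy differences of the 3 drugs from 0.01 to -0.21, 0.04 to -0.22 and 0.03 to -0.19, CBLB502 by irradiation from 0.02 to -0.18 and the tissue difference from -0.38 to 0.62. No scaling moved the vehicle arms from 0.04 to 0.18, amifostine to -0.06, amifostine at 8 Gy to -0.35, amifostine by irradiation from 0.04 to -0.45, CBLB502 by irradiation to -0.21, nilestriol by irradiation from 0.23 to -0.09 and tissue to -0.86. Quantile normalization moved bone marrow irradiation from 0.09 to -0.02, CBLB502 to 0.01, CBLB502 at 8 Gy to -0.08 and tissue to 0.32, and scaling over miRNAs detected on all 14 arrays moved amifostine and CBLB502 by irradiation to 0.23 and -0.10. Of the lists called in the 8 tests run on lists, the GC-rich list of the tissue difference alone changed the sign of its median with the scaling. A slide block could be fitted for the tissue difference alone, and leave-one-out fits could not be run for hypothalamus or for a lone drug array. Signal over background limits the dim miRNAs: 7.52% of tested bone marrow and 8.92% of hypothalamus values lay at the floor.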

Other observations

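The summaries per arm in this part, and the levels of tissue-restricted miRNAs, were looked at only after the results were seen, and no explanation was tested for them.

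In the nilestriol arm several list medians stood above those of the other arms after 8 Gy. Its stromal and endothelial list median was 1.40 higher at 8 than at 0 Gy, against -0.08 with PBS i.p., -0.11 with PBS i.g., 0.46 with amifostine and 0.05 with CBLB502. Muscle miRNAs, whose miR-1a-3p and miR-133 members mark striated muscle, stood at 1.55 with nilestriol and 0.91 with amifostine, against 0.10, -0.20 and -0.03 in the PBS i.p., PBS i.g. and CBLB502 arms. Progenitor miRNAs were at 0.96 with nilestriol and between 0.03 and 0.40 in the other arms. For nilestriol by irradiation no call was made, as given above. The 0 Gy nilestriol array stood apart by its nearest-array correlation (0.972, against at least 0.982 for the other 9). By its lowest correlation it did not.

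Responses to 8 Gy correlated between the PBS arms with r = 0.739 across 371 miRNAs, which are not independent replicates. The amifostine and CBLB502 responses correlated with r = 0.698, and nilestriol with the other arms from -0.01 to 0.46.

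Tissue levels set the background for miR-34a-5p, which was lower in bone marrow than in hypothalamus by a log2 difference of -2.00. The let-7 family was lower in bone marrow in 9 of 9 members, 8 past the threshold, with let-7e-5p at -6.95, and in the miR-15/16 family miR-15b-5p (5.32) and miR-16-5p (3.42) were higher there while miR-497-5p (-2.16) and miR-195a-5p (-1.31) were lower. As lists neither passed in camera (adjusted p = 0.0793 for let-7 and 0.0700 for miR-15/16). Oligodendrocyte miRNAs were lower in bone marrow in 4 of 4 members, all past the threshold, led by miR-219-2-3p (at least 5.03 lower; adjusted p = 0.0751 for the list).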
